A study of Homo sapiens with 8 samples.

How the data were processed

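The series profiled histone H3 lysine 4 methylation by chromatin immunoprecipitation and sequencing (ChIP-seq) in HEL, a human erythroleukemia cell line. Cells carried a doxycycline-inducible short hairpin RNA against LSD1 or a control hairpin and were harvested on day 4 of induction, per the labels' protocols. Of the 8 libraries, the 4 for H3K4me1 and H3K4me2 were analysed, 1 per condition and mark. The 4 panH3 and input libraries had no peak list and were not analysed here. Chromatin was crosslinked with formaldehyde and sheared by sonication, and libraries were sequenced on a NextSeq instrument, per the labels' protocols.

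Reads were aligned with BWA to hg19, per the submitters' processing notes. The deposited peak names give MACS2 as the peak caller. Its version, its options and the library used as background are not given in the sources used here. The authors deposited 1 peak list for each of the 4 H3K4me1 and H3K4me2 libraries. Every interval in the deposited lists is 1 bp long, so the lists hold peak summits, the position of highest enrichment of each peak, and no peak widths. The score deposited with each summit was read as the −log10 of the MACS2 q-value, because the scores begin just above 1.30, the −log10 of 0.05. Scores are the authors' own values. They depend on read depth as well as on enrichment, and were used to rank and filter summits within a list, in 1 case by the same score ranges in both control lists. Median scores are also given for both conditions, and the median on chromosome X relative to the autosomes was compared between lists. Read depth is not given in the sources used here, so the depth behind each list is unknown.

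The comparisons had been planned on peak intervals. Because the lists hold summits, each summit was widened by 250 bp on each side to a 501 bp window, and summits were matched when their windows overlapped, which means that they lay within 500 bp of each other. "Shared", "knockdown-only" and "control-only" refer to this matching within a mark. Covered length is the length of the union of these windows, so it follows the number and spacing of summits and carries no information on peak width. No hg19 annotation was used here, and the supplied gene table is of another build, so summits were not assigned to genes, promoters or introns. The planned comparisons of gene lists and genomic position were therefore not made. Under the rule fixed before the data were examined for this case, the 5 regions of 10 kb with the largest excess and the 5 with the largest deficit of covered length in the knockdown were named for each mark. Regions are given with 1-based hg19 coordinates.

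With 1 library per condition and mark, there is no spread between replicates and no test between conditions. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and not the variation between cultures or immunoprecipitations. Summits were also placed at random in their chromosomes 100 times, and displaced by 10 to 50 kb in either direction 100 times, to describe how often positions match by chance. The knockdown share of a set of summits is the number from the knockdown list divided by the number from both lists of the mark, and is 50% for lists of equal length.

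The alternatives planned before the data were examined were lists limited to the same number of top summits, to the same covered length, or to the upper 50% by score, matching within 250 or 1000 bp, merging of windows within 500 bp of each other, and chromosomes 1 to 22 alone. Matching within 2000 bp (2 kb), displaced places and their use under the other settings were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The matching code was tested on simulated lists made from the control summits, thinned to 56577 well separated sites for H3K4me1 and 50145 for H3K4me2, with known sites removed, added or moved by less than the matching distance. It found 100% of the sites removed and 100% of the 2000 sites added in each. Because these sites were well separated, the test checks the code only. It cannot show how often a lost site is matched to a neighbouring summit in the denser full lists.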

Results

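H3K4me1 and H3K4me2 were mapped in HEL erythroleukemia cells expressing a control hairpin or a hairpin against LSD1 (KDM1A), a histone demethylase that removes mono- and dimethyl groups from H3 lysine 4. H3K4me1 is typical of enhancers and of the flanks of promoters, and H3K4me2 of promoters and active enhancers. The study examined how knockdown of LSD1 affects H3K4 methylation in this cell line. Each condition and mark had 1 library, so the differences below could not be set against a spread between replicates, and no p-value is given. The intervals in brackets are exact 95% binomial intervals that cover counting error only. The lists held 111753 summits for control H3K4me1, 120268 for knockdown H3K4me1, 84268 for control H3K4me2 and 84650 for knockdown H3K4me2. Neither the level of LSD1 nor the read depth was measured by these lists.

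H3K4me1 was called at more places in LSD1 knockdown cells than in control cells, and H3K4me2 at nearly the same number. The knockdown list of H3K4me1 was 1.08 times as long as the control list, and that of H3K4me2 1.005 times. The knockdown share of all H3K4me1 summits was 51.8% (51.6 to 52.04%), against 50.1% (49.9 to 50.4%) for H3K4me2. The windows around H3K4me1 summits covered 55764 kb in control and 60052 kb in knockdown cells, and those around H3K4me2 summits covered 42041 and 42235 kb. The median score of the summits was 5.18 in the control and 5.11 in the knockdown list of H3K4me1, and 9.91 and 10.8 in those of H3K4me2. Summits of H3K4me1 lay closer together, with a median gap of 3016 bp in control cells against 5824 bp for H3K4me2.

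The share of H3K4me1 sites of control cells also found in knockdown cells depended on the matching distance. Of the control H3K4me1 summits, 60.8% (60.5 to 61.1%) had a knockdown summit within 500 bp, 43.2% (42.9 to 43.5%) had one within 250 bp, and 85.8% had one within 2000 bp. Conversely, 56.4% (56.1 to 56.7%) of knockdown summits had a control summit within 500 bp. When the control summits were placed at random, 4.19% matched, and when they were displaced by 10 to 50 kb, 12.6% did. This left 52407 knockdown-only and 43808 control-only H3K4me1 summits, of which 54.5% (54.2 to 54.8%) were knockdown-only. At the wider distance of 2000 bp, 22474 knockdown-only and 15835 control-only summits remained. The knockdown-only share follows the lengths of the lists, which depend on read depth as well.

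H3K4me1 sites called in 1 condition had lower scores in the median than shared sites. The median score was 5.97 for shared control H3K4me1 summits and 4.40 for control-only summits, and in the knockdown list 5.98 and 4.23. In the lowest score decile of the control list 47.2% (46.3 to 48.2%) of H3K4me1 summits were matched in knockdown cells, and in the highest decile 77.8% (77.0 to 78.5%). Within 2000 bp, 98.0% of the highest decile of the control list were matched, and 218 control summits and 256 knockdown summits of the highest deciles had no counterpart at that distance.

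**Figure D1:**
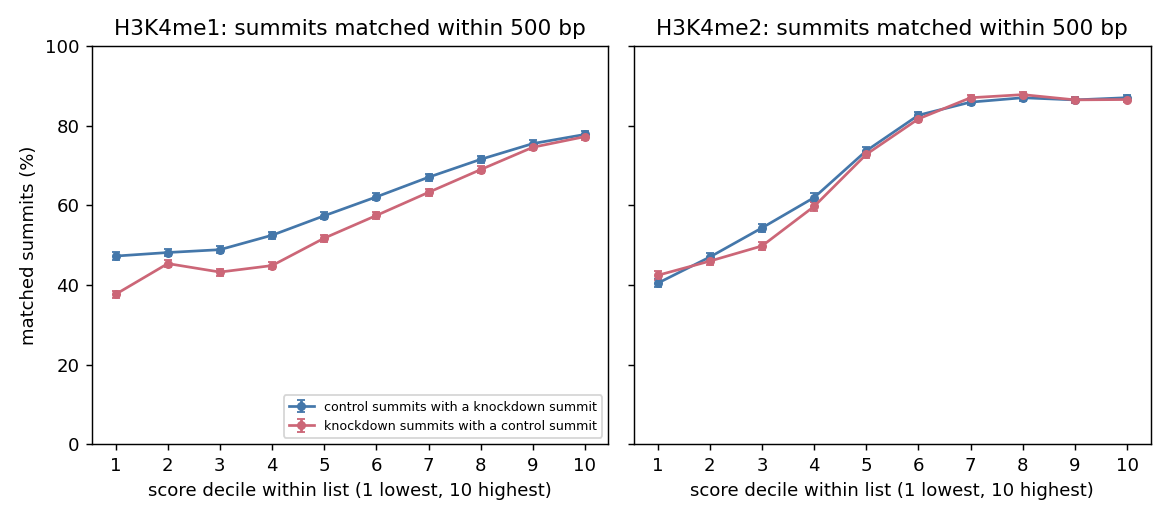
Share of summits with a summit of the other condition within 500 bp (y axis, percent) by score decile within each list (x axis), for H3K4me1 (left) and H3K4me2 (right). Points are single lists and bars are exact 95% binomial intervals; matching went from 47.2% to 77.8% for control H3K4me1 and from 40.4% to 87.0% for control H3K4me2 between the lowest and the highest decile.

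H3K4me2 sites were more often common to both conditions within 500 bp, and knockdown-only and control-only summits were nearly equal in number. A knockdown summit lay within 500 bp of 70.6% (70.3 to 70.9%) of control H3K4me2 summits, and a control summit within 500 bp of 70.0% (69.7 to 70.3%) of knockdown summits. Random placement gave 2.89% and displacement 6.70%. There were 25384 knockdown-only and 24747 control-only H3K4me2 summits, a knockdown-only share of 50.6% (50.2 to 51.1%). As for H3K4me1, this share follows the lengths of the lists, which were nearly equal. Within 2000 bp, 87.7% of control summits were matched, leaving 11814 knockdown-only and 10339 control-only summits. Shared control H3K4me2 summits had a median score of 14.0 and control-only summits 5.35. In the highest score decile 87.0% (86.3 to 87.7%) of control H3K4me2 summits were matched, against 40.4% (39.4 to 41.5%) in the lowest.

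Both marks are substrates of LSD1, and the state of each was compared at the sites where the other was called in 1 condition. At knockdown-only H3K4me2 sites, H3K4me1 lay within 500 bp at 45.7% (45.1 to 46.3%) of sites in control cells and at 53.1% (52.5 to 53.7%) in knockdown cells. At control-only H3K4me2 sites the order was the other way, with H3K4me1 at 46.9% (46.2 to 47.5%) in control and 41.9% (41.3 to 42.5%) in knockdown cells. At shared H3K4me2 sites the values were 45.9% and 45.1%. In all comparisons with the other mark, shared sites were taken at their knockdown summits. The shared control summits were not used, so a dependence of these values on the list chosen is unknown.

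Where H3K4me1 was called in 1 condition only near a knockdown-only H3K4me2 summit, it was called in the knockdown in 61.0% of 8531 cases (59.9 to 62.0%). Near control-only H3K4me2 summits this was 42.0% of 7639 cases (40.9 to 43.1%), and near shared ones 48.8% of 17167 cases (48.0 to 49.5%). Because the knockdown list of H3K4me1 was longer, summits displaced by 10 to 50 kb gave 54.8% (52.5 to 58.0% over the placements) for knockdown-only, 52.9% (50.2 to 54.8%) for control-only and 53.5% (51.6 to 54.97%) for shared H3K4me2 sites, so that the value at shared sites also lay below the range of displaced places. The value at knockdown-only H3K4me2 sites lay within the range of displaced places when summits were matched within 250 bp (55.1%, against 50.1 to 55.7%) and in the upper 50% of each list by score (55.3%, against 49.4 to 58.2%). The value at shared H3K4me2 summits passed to the other side of 50% when summits were matched within 1000 bp (52.8%) or 2000 bp (56.8%). Among the 11814 H3K4me2 summits of the knockdown with no control H3K4me2 summit within 2000 bp, H3K4me1 lay within 500 bp at 47.6% in control and 61.3% in knockdown cells. Among the 10339 control summits with no knockdown H3K4me2 summit within 2000 bp, H3K4me1 lay within 500 bp at 48.4% in control and 39.5% in knockdown cells.

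H3K4me2 at H3K4me1 sites had the same order. At knockdown-only H3K4me1 sites H3K4me2 was called at 21.1% (20.7 to 21.4%) in control and 25.5% (25.1 to 25.8%) in knockdown cells, and at control-only H3K4me1 sites at 28.5% (28.1 to 29.0%) and 25.5% (25.1 to 26.0%). Shared H3K4me1 sites had H3K4me2 more often, at 40.1% in control and 41.1% in knockdown cells. Randomly placed shared H3K4me1 sites met H3K4me2 at 2.91% and 2.93%. Where H3K4me2 was called in 1 condition only, the knockdown supplied 61.0% (60.1 to 61.9%) of calls at knockdown-only, 42.7% (41.7 to 43.7%) at control-only and 51.8% (51.1 to 52.5%) at shared H3K4me1 sites. Displaced summits gave 51.6% for knockdown-only and 49.5% for control-only H3K4me1 sites. In the upper 50% of each list by score, the value at control-only H3K4me1 sites was 45.6%, within the range of displaced places (44.5 to 53.8%).

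**Figure D2:**
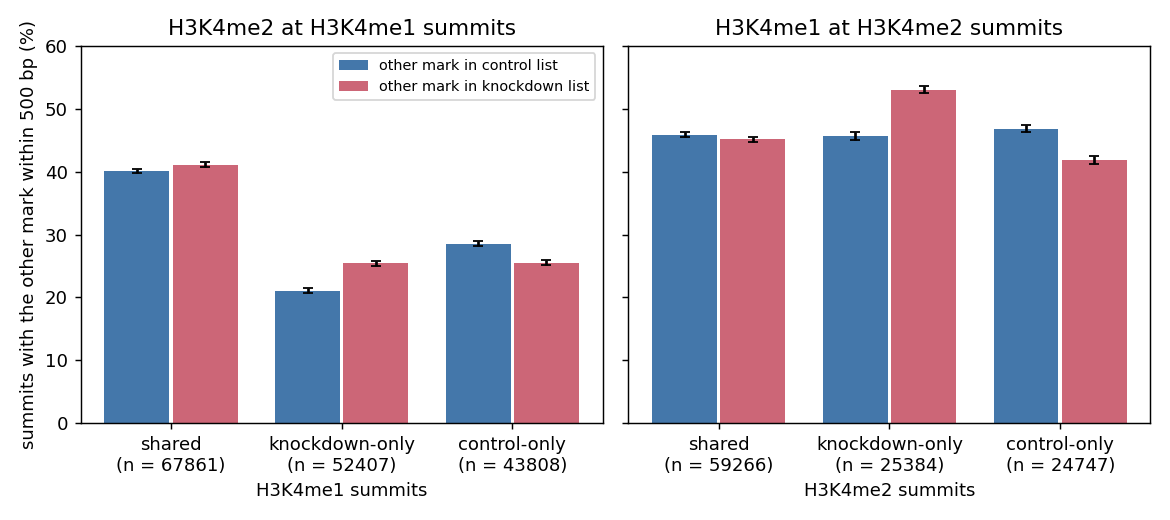
Share of summits with a summit of the other mark within 500 bp (y axis, percent) in the control list (blue) and the knockdown list (red), for shared, knockdown-only and control-only summits of H3K4me1 (left) and H3K4me2 (right). Bars are single lists with exact 95% binomial intervals; H3K4me1 was at 45.7% of knockdown-only H3K4me2 summits in control and 53.1% in knockdown cells.

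Over the full lists, chromosome X stood apart from the autosomes in the knockdown share of H3K4me1 summits and not in that of H3K4me2 summits. It held 647 H3K4me1 summits in control and 1211 in knockdown cells, a ratio of 1.87 and a knockdown share of 65.2% (63.0 to 67.3%). H3K4me2 summits on chromosome X numbered 2154 in control and 2176 in knockdown cells, a knockdown share of 50.3% (48.8 to 51.8%). In the upper 50% of each list by score the H3K4me2 share was 46.6% (43.8 to 49.4%). The median H3K4me2 score on chromosome X was 0.69 of the autosomal median in control and 0.60 in knockdown cells. The H3K4me1 summits on chromosome X had a median score of 3.67 in control cells, below the autosomal median of 5.18. With lists of equal length the knockdown share on chromosome X was 57.6% (55.1 to 60.1%).

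Among the autosomes, chromosome 7 had the highest ratio of knockdown to control H3K4me1 summits, with 4708 against 3892, a ratio of 1.21. Chromosome 14 followed with 3541 against 2988, a ratio of 1.19. Chromosome 21 alone had fewer H3K4me1 summits in knockdown cells, with 1596 against 1611, a knockdown share of 49.8% (48.0 to 51.5%). Ratios for H3K4me2 ranged from 0.95 on chromosome 13 to 1.04 on chromosome 3.

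**Figure D3:**
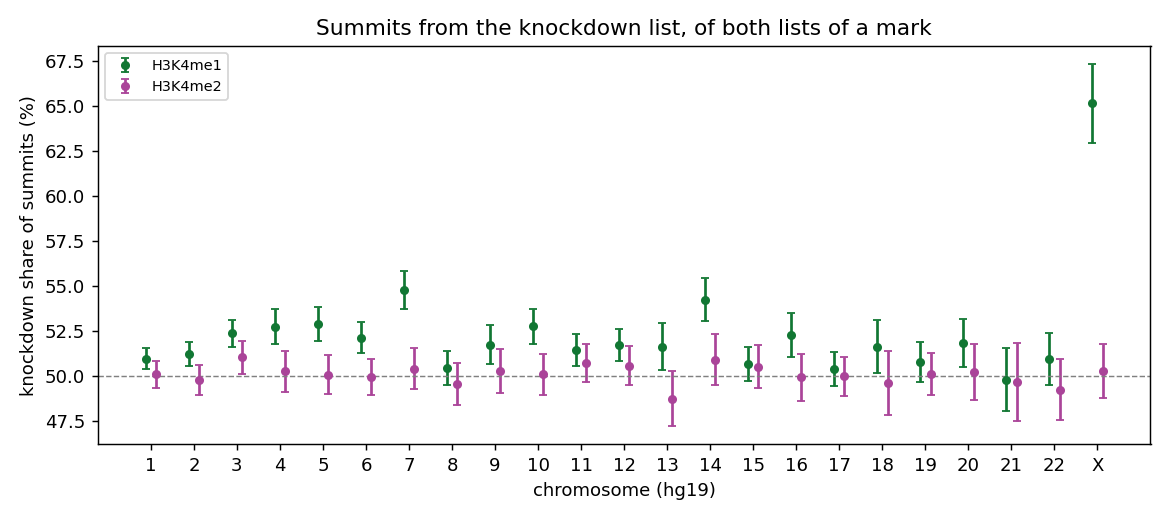
Knockdown share of the summits of both lists of a mark (y axis, percent; the axis does not start at 0) on each chromosome of hg19 (x axis). Points are H3K4me1 (green) and H3K4me2 (purple) with exact 95% binomial intervals, and the dashed line marks 50%; H3K4me1 on chromosome X was at 65.2%.

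The regions with the largest H3K4me1 excess in knockdown cells were found by covered length in 10 kb steps, so their values are extremes by selection. On chromosome 7, the region from 35860001 to 35870000 had 1 H3K4me1 summit in control and 10 in knockdown cells, and H3K4me2 had 0 and 1. A second region of chromosome 7, from 131970001 to 131980000, had 0 and 8 H3K4me1 summits, together with 0 and 2 H3K4me2 summits. The region from 86140001 to 86150000 on chromosome 9 had 3 and 10 H3K4me1 summits, that from 30500001 to 30510000 on chromosome 16 had 0 and 7, and that from 118810001 to 118820000 on chromosome X had 2 and 9. In these last 3 regions H3K4me2 summits numbered 4 and 5, 1 and 2, and 4 and 4 in control and knockdown cells.

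The largest H3K4me1 deficits in knockdown cells were in 5 other regions. On chromosome 8, from 98790001 to 98800000, control cells had 8 H3K4me1 summits and knockdown cells 1, while H3K4me2 had 3 and 5. The region from 120440001 to 120450000 on chromosome 11 also had 8 and 1, and that from 43740001 to 43750000 on chromosome 3 had 8 and 2. On chromosome 17 the region from 80190001 to 80200000 had 9 and 3 H3K4me1 summits and 2 and 0 H3K4me2 summits, and the region from 40560001 to 40570000 had 8 and 2 H3K4me1 summits and 1 and 3 H3K4me2 summits.

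For H3K4me2, the largest excess in knockdown cells lay on chromosome 19 from 16250001 to 16260000, with 3 summits in control and 9 in knockdown cells. The region from 80610001 to 80620000 on chromosome 9 had 2 and 8 H3K4me2 summits while its H3K4me1 summits numbered 8 and 3. The regions from 108740001 to 108750000 on chromosome 5, from 69010001 to 69020000 on chromosome 12 and from 117430001 to 117440000 on chromosome 7 had 2 and 8, 2 and 7, and 4 and 9 H3K4me2 summits. Among the upper 50% of each list by score, the last of these had 2 control summits and no knockdown summit, so its direction turned.

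The largest H3K4me2 deficit lay on chromosome 18 from 9920001 to 9930000, with 12 summits in control and 5 in knockdown cells and 8 H3K4me1 summits in both. On chromosome 16 the region from 89550001 to 89560000 had 8 and 2 H3K4me2 summits and 7 and 4 H3K4me1 summits. The region from 23390001 to 23400000 on chromosome 8 and that from 161670001 to 161680000 on chromosome 6 each had 7 and 1 H3K4me2 summits. On chromosome 1 the region from 65750001 to 65760000 had 10 and 4 H3K4me2 summits and 7 and 3 H3K4me1 summits. In the upper 50% by score, the regions of chromosomes 5, 16 and 6 named for H3K4me2 had as many control as knockdown summits, and those of chromosomes 12 and 8 had none.

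**Figure D4:**
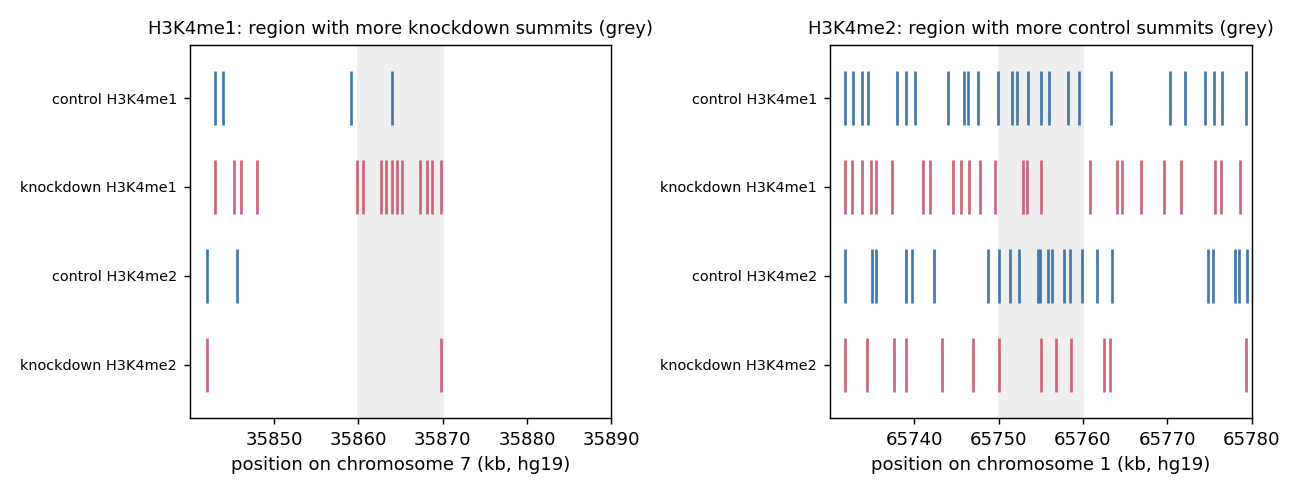
Positions of summits (x axis, kb of hg19; each tick is 1 summit) in the 4 lists (rows) around 2 named regions of 10 kb, shaded grey. Left, the region of chromosome 7 with 1 control and 10 knockdown H3K4me1 summits; right, the region of chromosome 1 with 10 control and 4 knockdown H3K4me2 summits.

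Over the genome, 77869 regions of 10 kb held window length of at least 1 list. In 5557 of them H3K4me1 covered at least 1000 bp more in knockdown than in control cells, and in 3730 at least 1000 bp less. The same held for 1870 and 1752 regions of H3K4me2. Both marks covered more in 348 regions, against 133 if the marks differed independently over all regions, and both covered less in 216, against 83.9. Regions of opposite direction were also above that number, with 180 of more H3K4me1 and less H3K4me2, against 125, and 148 of the reverse, against 89.6. The number for independent marks treats all regions alike, although regions with more summits can differ more in both marks. Of the 892 regions where both differed, 63.2% (59.97 to 66.4%) had the same direction. The interval included 50% in the upper 50% of each list by score (59.0%, 49.7 to 67.8%, 122 regions) and with windows for matching within 250 bp (53.3%, 26.6 to 78.7%, 15 regions).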

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

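The tests of copies of chromosome X and of the trend across autosomes were chosen only after the result was seen. The knockdown and control lists differed in opposite directions for the 2 marks on 8 chromosomes and, by covered length, in 9 named regions. These differences were not tested. On each of these chromosomes the knockdown share of summits was above 50% for H3K4me1 and below 50% for H3K4me2. The counting interval of H3K4me2 included 50% on each of them, and that of H3K4me1 did so on chromosomes 8, 17 and 22. These intervals ignore that many summits were matched between the lists, so they do not settle either direction. The difference between the marks was 1.45 percentage points on chromosome 2, 2.19 on chromosome 6, 0.89 on chromosome 8, 2.88 on chromosome 13, 2.33 on chromosome 16, 0.41 on chromosome 17, 2.02 on chromosome 18 and 1.71 on chromosome 22.

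In the named regions, the change of covered H3K4me1 length from control to knockdown minus that of H3K4me2 was 3580 bp in the chromosome X region from 118810001. It was -4576 bp in the chromosome 8 region from 98790001, -3920 bp in the chromosome 11 region from 120440001 and -3992 bp in the chromosome 17 region from 40560001. It was -4140 bp in the chromosome 19 region from 16250001, -5471 bp in the chromosome 9 region from 80610001 and -3898 bp in the chromosome 12 region from 69010001. It was 3280 bp in the chromosome 18 region from 9920001 and 3172 bp in the chromosome 8 region from 23390001. In the chromosome X region H3K4me2 had 4 summits in both conditions and changed by -110 bp. In the chromosome 18 region and the chromosome 8 region from 23390001, H3K4me1 had 8 summits in both conditions. It changed there by 38 and 173 bp. In these regions the difference therefore came almost wholly from 1 mark.

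The H3K4me1 excess on chromosome X, with 1211 knockdown against 647 control summits, was weighed against technical explanations. H3K4me2 gave no sign of more copies of chromosome X in the knockdown culture. Its knockdown share there was 50.3%, and 46.6% (43.8 to 49.4%) in the upper 50% of each list by score. Its median score on X relative to the autosomes was 0.875 times as high in the knockdown as in the control list. Whether H3K4me2 summits follow copy number was not tested, and the background library is unknown, so these values do not exclude this cause. A position near the detection limit, where a slightly more sensitive library adds many weak sites, is another candidate. Across the 22 autosomes, those with weaker control H3K4me1 summits had higher knockdown shares (Spearman's rho -0.79, Pearson's r -0.79, and rho -0.72 without chromosomes 7 and 21). Chromosomes are not independent replicates. Both values come in part from the control list, so a weaker control signal for any reason would give this sign. The trend therefore cannot single out the detection limit. Lists of equal length leave out the weakest knockdown H3K4me1 summits. With them, X held 879 knockdown against 647 control summits, a knockdown share of 57.6% (55.1 to 60.1%). Much of the excess therefore lay among the weakest calls. In the upper 50% of each list by score, the knockdown share on X was still 61.4% (55.5 to 67.0%, 290 summits). This interval is too wide to decide whether the detection limit is the whole cause. A response of chromosome X to the knockdown itself stays open and was not tested.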

How the results depend on the processing

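No replicates exist, so leaving out a library was not possible. No paired analysis was possible because each group has 1 library. Matching within 2000 bp, and every alternative for chromosome X, the 10 kb regions and most of those for the other mark, were chosen after seeing the data. Other promoter widths, all transcript starts, other windows around genes and means over gene lists were not run, because no annotation of hg19 was used. The unknown read depth limits every count of summits. With chromosomes 1 to 22 alone, all 15 main values computed stayed within their counting intervals or, for numbers of summits, within 1.5 times. Over all settings, 54 of the main values stayed within these bounds, 62 moved and 1 passed to the other side. Of the values for single regions, shared sites, knockdown matching and H3K4me2 on chromosome X, 64 stayed within these bounds, 27 moved and 3 passed to the other side. For single regions this tally tests little, because counting intervals from 7 to 17 summits are wide. In the upper 50% by score, the knockdown share in the H3K4me2 regions of chromosomes 5, 16 and 6 went from 80, 20 and 12.5 to 50. These regions were still counted as within the bounds. Values are in percent, with "call share" for the knockdown share of calls of the other mark made in 1 condition; the cause was not tested beyond what each setting does by construction.

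With the same number of top summits, the H3K4me1 knockdown share was 50% and the knockdown-only share 50.3, both by construction, control matching 58.2, H3K4me1 call share 58.2 at knockdown-only and 38.5 at control-only H3K4me2 summits, and the chromosome X share 57.6. With the same covered length these were 49.96 (the other side of 50), 50.2, 58.1, 58.1, 38.5 and 57.6. With windows within 500 bp merged, the H3K4me1 knockdown share was 52.1, control matching 65.6 for H3K4me1 and 74.6 for H3K4me2, the knockdown-only shares 55.4 and 51.1, H3K4me2 call share at knockdown-only H3K4me1 sites 62.8, and H3K4me1 call share 62.6 at knockdown-only and 40.6 at control-only H3K4me2 sites. In the upper 50% by score, control matching was 51.5 for H3K4me1 and 74.7 for H3K4me2, the H3K4me1 knockdown-only share 53.7, H3K4me2 call share 57.7 and 45.6 at knockdown-only and control-only H3K4me1 sites, H3K4me1 call share at knockdown-only H3K4me2 sites 55.3, the chromosome X share 61.4, and the same-direction share of regions 59.0 (49.7 to 67.8). The numbers of knockdown-only and control-only summits were then 31371 and 27099 for H3K4me1 and 10851 and 10642 for H3K4me2, with 50% of each list removed, and the chromosome 7 region from 117430001 had a knockdown share of 0, from 2 summits.

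Matching distance moved most values. Within 250, 1000 and 2000 bp, control matching was 43.2, 77.0 and 85.8 for H3K4me1 and 57.6, 81.1 and 87.7 for H3K4me2, and the H3K4me1 knockdown-only share 53.2, 56.8 and 58.7. The H3K4me2 knockdown-only share was 51.8 and 53.3 within 1000 and 2000 bp. H3K4me2 call share was 57.5, 68.4 and 78.5 at knockdown-only and 46.7, 36.2 and 26.9 at control-only H3K4me1 sites. H3K4me1 call share was 55.1, 73.4 and 83.1 at knockdown-only and 44.1, 37.4 and 30.6 at control-only H3K4me2 sites, against 53.1, 57.8 and 60.9 and 52.2, 53.5 and 54.0 at displaced places. The 55.1 lay within the range of displaced places (50.1 to 55.7), as did the 55.3 of the upper 50% by score (49.4 to 58.2). At shared H3K4me2 sites the H3K4me1 call share passed to the other side, with 52.8 and 56.8 within 1000 and 2000 bp. With windows for 250 bp, the same-direction share of regions was 53.3 (26.6 to 78.7), from 15 regions. Within 1000 bp there were 33729 knockdown-only and 25653 control-only H3K4me1 summits and 15893 control-only H3K4me2 summits. Within 2000 bp there were 22474 and 15835 for H3K4me1 and 11814 and 10339 for H3K4me2.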

Other observations

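The tests of moved summits, of equal score ranges and of knockdown-only against control-only sites at displaced places, and the values of the first paragraphs, were chosen only after the result was seen. The strongest H3K4me2 summits less often had H3K4me1 within 250 bp and more often within 2000 bp. In control cells an H3K4me1 summit lay within 250 bp of 33.7% of H3K4me2 summits in the lowest score decile and of 16.5% in the highest, whereas within 2000 bp the shares were 72.6% and 81.7%. In knockdown cells the shares within 250 bp were 35.7% and 13.6%, and within 2000 bp 77.7% and 81.1%. The 5 regions of 10 kb where both marks were most reduced in knockdown cells included chromosome 2 from 27620001 to 27630000, with 4 H3K4me1 and 4 H3K4me2 summits in control and 0 of either in knockdown cells, and chromosome 4 from 48230001 to 48240000, with 7 and 3 H3K4me1 and 10 and 5 H3K4me2 summits. Those where both were most increased included chromosome 14 from 93310001 to 93320000, with 1 and 6 H3K4me1 and 1 and 5 H3K4me2 summits, and chromosome 7 from 30330001 to 30340000, with 2 and 8 H3K4me1 and 0 and 4 H3K4me2 summits.

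Alternate haplotype sequences of chromosome 6 held 906 control and 876 knockdown H3K4me2 summits, 1.08% and 1.03% of their lists. They held 15 control and 37 knockdown H3K4me1 summits, 0.013% and 0.031%. Why the marks differ there was not tested, and comparisons between the marks carry this unlike treatment or signal.

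H3K4me1 and H3K4me2 tended to differ in the same direction at the same places, in separate immunoprecipitations. With full lists matched within 500 bp, broad segments that differ between the cultures, such as copy number, are argued against as the whole cause. The call share differed by 19.0 percentage points between knockdown-only and control-only H3K4me2 sites. At places displaced by 10 to 50 kb it differed by 1.83 (at most 7.80 over the placements). An earlier comparison of knockdown-only sites alone, 6.22 points above displaced places, had fallen between its bounds. Within 250 bp the knockdown-only value was 55.1%, inside the displaced range (50.1 to 55.7%). It was also inside in the upper 50% by score (49.4 to 58.2%), so the argument fails there for knockdown-only sites. Control-only values lay below their range in both settings. Within 1000 and 2000 bp, and with the same number of top summits, both values lay outside. Weak summits crossing the threshold may contribute, since the share at knockdown-only H3K4me2 sites was 55.3% (53.5 to 57.1%, 53.8% at displaced places) in the upper 50% by score; at control-only sites it was 43.1%, below the 46.1 to 58.8% of displaced places, and a filter on score sets a threshold of its own, which keeps this open. Differences between the cultures other than the knockdown cannot be told apart from it with 1 library per condition and mark, and a background library common to both marks of a condition, if one was used, would act in the same way. An effect of LSD1 loss on both marks at the same sites is a hypothesis that these lists leave open.

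A smaller share of H3K4me1 than of H3K4me2 summits had a counterpart within 500 bp. Within 5000 bp the shares of the control lists were nearly equal, at 92.0% and 92.3%. Summits that move within broad H3K4me1 domains are 1 candidate explanation, which the values leave open. Of unmatched control H3K4me1 summits, 63.9% had a knockdown summit within 2 kb, against 32.0% at displaced places. So did 58.2% of unmatched control H3K4me2 summits, against 20.5%. The excess over displaced places was thus smaller for H3K4me1, at 31.9 points against 37.7, although this explanation called for a larger one. Lower scores of H3K4me1 are another, also left open: at control scores from 5 to 10 the marks were matched at 66.4% and 66.7%, a difference of 0.31 percentage points, but at scores from 10 to 20 they were matched at 76.9% and 84.3%, and at scores from 3 to 5 at 51.7% and 46.7%. No biological explanation was tested.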
